A study of Mus musculus with 150 samples.

How the data were processed

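Messenger RNA of perfused livers, selected by polyA tails and read as paired ends, was measured in mice of the BXD family that differed in diet, age and strain. The authors mapped the reads with STAR 2.6.0c to GRCm38/mm10, the C57BL/6J genome, with basic GENCODE transcripts, 1 row per transcript, and did not state how reads were counted. The deposited values are FPKM, normalised per kilobase of transcript and for the number of mapped reads, and a second deposited table holds the other unit, log2(FPKM + 1). Both tables have 150 columns and 43320 transcripts of 25394 gene symbols. The log2 table was checked against the FPKM table, and every value lay within 0.0005 of log2(FPKM + 1). For the 17311 transcripts whose version was in GENCODE M21, 100% of values above 0 came to a whole number of reads, within 0.02 of a read. For that check the size of 1 read was taken from the smallest values of each library. In all but the 7 columns that repeat another library, it matched the header's total of uniquely plus multiply mapped reads. Isoforms of a gene had like values, so reads appear to be shared between them and not divided.

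Each gene was represented by the transcript with the most reads over all mice (mean FPKM times its GENCODE M21 length). Starts in the table lay 1 base before those of GENCODE M21 and were moved to 1-based positions. Of the 150 columns, 7 repeated another library's values exactly and were left out, since they hold no measurement of their own. The remaining 143 libraries came from 141 mice labelled female and 2 males, and the males were left out of all fits but 1 alternative. Some genes of the marker lists, such as Igkc, were not analysed here, and Cidea did not pass the level filter. The adipocyte list had 2 measured genes and was not tested.

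Libraries held 18330270 to 35274551 input reads. An FPKM of 1 on a transcript of 1 kb stood for 16.7 to 32.1 reads, which sets the counting error of low values. Genes with a mean FPKM of at least 0.5 were kept, which left 13304.

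The tests used limma 3.58.1 in R 4.3.3 with statmod 1.5.0. limma-trend (lmFit, then eBayes with trend and robust variances) was fitted to log2(FPKM + 1) with terms for diet, age in days and strain as a fixed factor, with 99 residual degrees of freedom. Age slopes are given per year. Diet, age, the diet by age interaction, the parents and the reciprocal F1 hybrids were tested by moderated statistics, and strain and strain by diet by moderated F-tests. Strain by diet used 132 mice of 35 strains, with 34 and 61 degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with calls at an adjusted p under 0.05. A log2 change is a fitted difference on the log2(FPKM + 1) scale and can be smaller than the ratio of mean FPKM for low genes.

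Gene lists, 39 with at least 3 measured genes, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation beside it, and with fry. Adjustment was over the lists of each comparison. Counts adjusted over the list alone use the Benjamini-Hochberg method within that list. The lists were written by hand from general knowledge and not from these samples. Some genes stand in more than 1 list, and leukocyte markers are also expressed by cells that reside in liver.

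Named genes followed a rule. For diet and for age these were the 8 largest rises and the 8 largest falls among genes past the test with a mean FPKM of at least 1, and the 3 genes with the smallest p of each list called by camera. A further set was reported whatever its p. For the interaction they were the 10 genes with the smallest p, for strain the 12 with the largest share of variance, for the parents the 6 largest changes each way, and for the F1 up to 6 genes past the test. Predicted genes with symbols of Gm and digits or ending in Rik were passed over, and some genes that the rule picks are not reported here. Strain direction counts use the 35 strains with both diets for diet, and the 34 strains spanning at least 150 days for age.

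The model, filter, pseudocount, lists, named gene rule and the first set of alternatives were chosen before the data were examined. That set held a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios rescaling, the log2 table, collection session or position within the collection day as a term, strain as a random effect or no strain term, the males included, mice over 600 days left out, arrayWeights, age as 18-month against 7-month class, and the estimated correlation. Collection session was read from the case identifier as a date, which is an assumption. Chosen after seeing the data were the 7 repeated columns included, flow cell as a factor, other choices of transcript, limma-voom on recovered reads, the length slope of each library as a covariate, each parent or F1 mouse left out in turn, and 2 sets of libraries left out. The first of these sets was 1 mouse labelled female whose sex-linked levels were male-like, and the second was 8 libraries over 3.5 robust SD out on the first principal component.

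The workflow was tested on simulated data with this design, with 100 genes changed at each of 2 sizes. Each gene was given independent normal noise, so the simulation held no correlation between genes and no libraries or sessions that stood apart. For diet, 93% of genes changed by 0.5 log2 and 100% of those changed by 1 were recovered, and for age 99 and 100%. Changes of 1 log2 were recovered for 68% of genes between the parents and 79% between the F1. From 4.4 to 8.4% of calls were false. A list of 30 genes shifted by 0.3 log2 had a camera p of 8.01e-55, and 0% of 500 unshifted lists had p under 0.05. This list result does not cover lists of correlated genes. Quality measures of both diets were compared by 2-sided permutation tests with 100000 resamples, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading files and drawing.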

Results

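Liver mRNA was measured in mice of the BXD family, a set of recombinant inbred strains bred from the inbred strains C57BL/6J and DBA/2J, with both parents and their reciprocal F1 hybrids, B6D2F1 and D2B6F1. The mice ate a chow diet (CD) or a high-fat diet (HF). The comparisons below use 141 mice labelled female, 1 of them with male-like levels of sex-linked genes, of 40 strains, 72 on CD and 69 on HF, with 1 to 6 mice per strain. By age at collection, 53 mice were 157 to 261 days old (the 7-month class), 20 were 291 to 386 days, 58 were 460 to 630 days (the 18-month class) and 10 were 640 to 764 days. On CD these classes held 27, 11, 28 and 6 mice, and on HF 26, 9, 30 and 4. The libraries held 18330270 to 35274551 input reads, of which 79.8 to 90.68% mapped to 1 place. An FPKM of 1 on a transcript of 1 kb stood for 16.7 to 32.1 reads. Coordinates are on the mouse genome build GRCm38, for the transcript that stood for each gene.

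The first question was how the livers of mice on HF differed from those on CD of the same age and strain. On HF, some enzymes that clear drugs were lower, as was Cyp26a1, and several lipid-handling genes were higher. Cyp2b10, a cytochrome P450 known as a target of the xenobiotic receptor CAR (chromosome 7, 25897620 to 25926624), averaged 7.17 FPKM ± 6.59 (SD, n = 72) on CD and 0.646 FPKM ± 0.615 (SD, n = 69) on HF. Cyp26a1, which breaks down retinoic acid (chromosome 19, 37697808 to 37701528), averaged 26.3 ± 20.4 FPKM on CD and 8.28 ± 5.90 FPKM on HF. Apoa4, an apolipoprotein of triglyceride-rich particles (chromosome 9, 46240696 to 46243459), averaged 302 ± 215 FPKM on CD and 778 ± 1177 FPKM on HF.

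In the limma fit, 1345 of 13304 genes passed an adjusted p of 0.05 for diet, 608 higher and 737 lower on HF. Changes were small for most, with 40 genes higher and 76 lower by at least 0.5 on the log2 scale, and 0 higher and 13 lower by at least 1. The log2 change of Cyp2b10 was -1.92 (SE 0.14, limma adjusted p = 5.3e-20), and it was higher on HF in 3 of the 35 strains with both diets. That of Cyp26a1 was -1.46 (SE 0.13, limma adjusted p = 1.56e-16), higher on HF in 1 of 35 strains. Ces2a, a carboxylesterase, changed by -1.16 (SE 0.10, adjusted p = 7.03e-16). The other large falls were Hamp, the iron hormone hepcidin (log2 change -2.09, adjusted p = 3.67e-06), Gsta2 (-1.53), A1bg (-1.46), Cyp3a11 (-1.41) and the sulfotransferase Sult2a1 (-1.16). Apoa4 rose by 0.94 (SE 0.14, adjusted p = 5.34e-07, higher in 30 of 35 strains), Wfdc2 by 0.86 (SE 0.11, adjusted p = 2.05e-09, 33 of 35) and Fabp2, a fatty acid binding protein, by 0.83 (SE 0.11, adjusted p = 3.04e-08, 32 of 35). Fgf21, a hormone released by the liver (0.93), the organic anion transporter Slc22a7 (0.83), the deiodinase Dio1 (0.80), the imprinted RNA H19 (0.84) and Mir675, which lies within H19 (0.84), also rose. Gsta2, Hamp and the Cyp genes have close paralogs that share reads, so part of a change can belong to a relative.

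**Figure D1:**
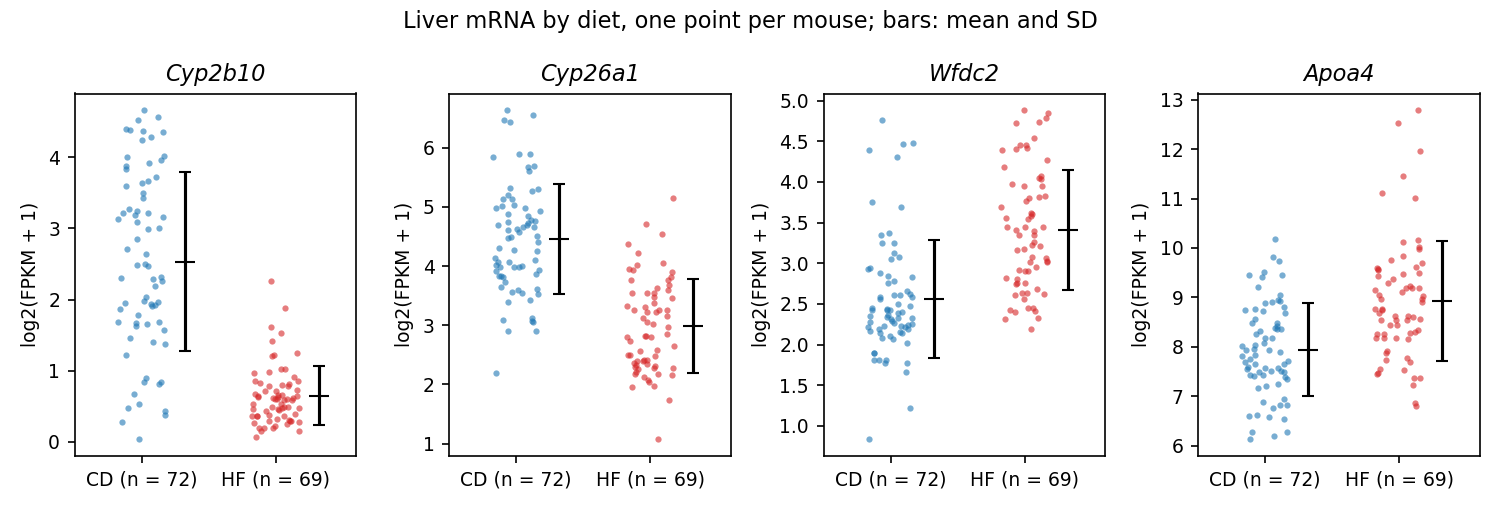
Levels of Cyp2b10, Cyp26a1, Wfdc2 and Apoa4 as log2(FPKM + 1) on the vertical axis, with 1 point per mouse for 72 mice on CD and 69 on HF and bars for mean and SD. Cyp2b10 and Cyp26a1 lie lower on HF (log2 changes -1.92 and -1.46), Wfdc2 and Apoa4 higher (0.86 and 0.94), and the points of both diets overlap.

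Among detoxification genes, the list of xenobiotic cytochromes P450 also holds the receptors Nr1i2 and Nr1i3 and the reductase Por. Of its 26 measured genes, 12 fell and 1 rose (2 rose and 13 fell adjusted over the list alone). Examples are Cyp3a11, which averaged 662 ± 424 FPKM on CD and 250 ± 170 FPKM on HF, and Cyp2c54 (log2 change -1.07). The list as a whole ranked below other genes (median -0.37, camera adjusted p = 6.94e-10, and adjusted p = 0.299 with an estimated correlation). Of 24 glutathione and NRF2 target genes, 11 fell (14 adjusted over the list alone), among them Gstm3 (-0.92) and Ugdh (-0.45), with camera adjusted p = 6.84e-10 and adjusted p = 0.24 with an estimated correlation. Major urinary proteins, pheromone carriers made in liver, fell for 13 of 18 measured genes on either adjustment, such as Mup2 (-0.80) and Mup1 (-0.92), with camera adjusted p = 4.64e-08 and adjusted p = 0.474 with an estimated correlation. Many of these genes are near-identical copies, whose reads cannot be given to single members with certainty.

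Lipid and glucose genes moved in both directions. Of 24 genes of cholesterol synthesis and uptake, 4 fell on either adjustment, with Tm7sf2 (-0.54), Pmvk (-0.57) and Cyp51 (-0.47) having the smallest p, while Sqle (-0.33, adjusted p = 0.13) did not pass. That list had camera adjusted p = 2.12e-05 and adjusted p = 0.582 with an estimated correlation. Of 18 genes of de novo lipogenesis, 4 rose and 1 fell (6 and 1 adjusted over the list alone). Fads2 rose from 205 ± 126 to 320 ± 170 FPKM (log2 change 0.59), and Pklr by 0.57, whereas Fasn (0.28, adjusted p = 0.344) and Scd1 (-0.26, adjusted p = 0.477) did not pass. The lipogenesis list had camera adjusted p = 0.00114 and adjusted p = 0.582 with an estimated correlation. Of 28 genes of fatty acid oxidation and PPAR-alpha targets, 5 rose (10 adjusted over the list alone), including Ppara (0.42), Vnn1 (0.59) and Cpt1a (0.37), but Pdk4 did not pass (-0.07). The camera adjusted p was 1.67e-06, and adjusted p = 0.546 with an estimated correlation. Of 13 lipid droplet and PPAR-gamma target genes, 2 rose, Plin4 (0.54) and Mogat1 (0.31), and 3 adjusted over the list alone. Plin2 (0.25), Cidec (0.29), Cd36 (0.12) and Pparg (0.14) did not pass. This list had camera adjusted p = 0.000264 and adjusted p = 0.413 with an estimated correlation. Of 20 glucose genes, 5 rose on either adjustment, such as Foxo1 (0.24) and Ppp1r3b (0.39), with camera adjusted p = 0.0106 and adjusted p = 0.519 with an estimated correlation. Of 25 amino acid and urea cycle genes, 1 rose, Glul (0.38), and 2 fell, Hal (-0.40) and Asl (-0.27), or 1 and 4 adjusted over the list alone. The camera adjusted p was 0.0138, and adjusted p = 0.809 with an estimated correlation.

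Of 75 cytosolic ribosomal protein genes, 46 fell on HF and 0 rose (74 and 0 adjusted over the list alone). The median log2 change was -0.21, for example Rpl12 from 155 ± 104 to 110 ± 35.4 FPKM (-0.34), with camera adjusted p = 7.36e-27 and adjusted p = 0.474 with an estimated correlation. With the length slope of each library as a covariate the median was -0.106 and 29 genes fell. Across 13212 genes, which are not independent replicates, the diet change was higher for longer transcripts (Spearman's rho 0.3), and ribosomal protein transcripts are short. The 31 proteasome genes had 5 falls (11 adjusted over the list alone), such as Psmc1 (-0.12), with camera adjusted p = 3.56e-07 and adjusted p = 0.513 with an estimated correlation. None of 75 nuclear oxidative phosphorylation genes passed limma (0 adjusted over all genes, 0 adjusted over the list alone, and 1 up and 8 down at an unadjusted p under 0.05), although the list ranked lower by camera (adjusted p = 0.0122, and adjusted p = 0.923 with an estimated correlation). Its smallest p belonged to Ndufb5 (-0.12, adjusted p = 0.112), and the median changed sign from -0.05 to 0.03 once the length slope was a covariate.

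Heat shock genes rose for 7 of 10 on either adjustment, including Hsph1 (0.50), Dnaja1 (0.29) and Hspa1b (0.55), with camera adjusted p = 6.92e-05 and adjusted p = 0.382 with an estimated correlation. Of 36 interferon-stimulated genes, 12 rose (18 adjusted over the list alone), such as Ifi44 (0.41) and Dhx58 (0.27), with camera adjusted p = 6.94e-10 and adjusted p = 0.474 with an estimated correlation. Of 18 circadian clock genes, 4 rose (7 rose and 1 fell adjusted over the list alone), led by Per2 (0.53) and Per3 (0.48), with camera adjusted p = 0.00461 and adjusted p = 0.474 with an estimated correlation. Of 17 p53 and senescence genes, 2 rose, Gdf15 (0.43) and Zmat3 (0.15), and 3 adjusted over the list alone, with camera adjusted p = 0.0104 and adjusted p = 0.546 with an estimated correlation. The 24 extracellular matrix genes held 0 calls by limma on either adjustment (4 up at an unadjusted p under 0.05), with Col6a1 nearest (0.26, adjusted p = 0.0868), and camera adjusted p = 0.00769 and adjusted p = 0.867 with an estimated correlation. Among markers of other cells, the erythroid list ranked higher on HF, with 1 of 5 genes past the test, Alas2 (0.40), or 5 adjusted over the list alone. Its camera adjusted p was 0.00369, and adjusted p = 0.479 with an estimated correlation. Exocrine pancreas markers, which liver should hardly express, had a median log2 change of 0.47 with 0 of 13 genes past limma on either adjustment (0 at an unadjusted p under 0.05), Cela1 averaging 50.1 ± 88.6 FPKM on CD and 60.1 ± 91.0 FPKM on HF. Their camera adjusted p was 0.0272, and adjusted p = 0.886 with an estimated correlation.

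Camera called 19 of 39 lists for diet with its preset correlation and 0 with an estimated one, and fry, which asks only whether a list's own genes moved on balance 1 way, called 11. Among uncalled lists the median, mean and test differed in sign for acute phase (0.08, -0.02, up), antigen presentation (0.05, -0.08, down) and neutrophil markers (0.05, 0.02, down), and the median and test for sinusoidal endothelial markers (-0.025, up). Uniquely mapped reads were 85.9 ± 2.67% on CD and 87.1 ± 2.12% on HF (2-sided permutation p = 0.00302, adjusted over 7 quality measures 0.0211). The length slope of a library, the rise of its log2 levels over the mean of all libraries per doubling of transcript length, was -0.0116 ± 0.0700 on CD and 0.0122 ± 0.0490 on HF (p = 0.0205, adjusted 0.0719). With flow cell as a factor 1363 genes passed for diet. Among the genes named above, at least 1 alternative ended the calls of Vnn1, Cpt1a, Gdf15 and Zmat3. Among the lists, alternatives beside the estimated correlation ended or turned those of fatty acid oxidation, glucose, amino acid, oxidative phosphorylation, p53, extracellular matrix and exocrine pancreas genes.

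The next question was how liver mRNA changed with age at a given diet and strain. Many genes of white blood cells, inflammation, cell division and growth arrest rose with age, and major urinary proteins and some genes of several metabolic lists fell. The counts are given below, and of all these lists camera called the major urinary proteins alone with an estimated correlation. Mup13 (chromosome 4, 61224307 to 61228286) averaged 164 ± 122 FPKM in the 7-month class (n = 53) and 52.7 ± 63.4 FPKM in the 18-month class (n = 58). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29093772 to 29100722), averaged 4.55 ± 3.97 and 14.8 ± 18.4 FPKM. Cdkn2a, the locus of the senescence marker p16 (chromosome 4, 89274541 to 89294653), averaged 0.490 ± 0.482 and 2.54 ± 5.69 FPKM. Isoforms of a gene appear to share reads, so this level cannot be given to the p16 transcript alone. Lcn2, an iron-binding protein of the acute phase (chromosome 2, 32384633 to 32387797), averaged 116 ± 377 and 302 ± 656 FPKM.

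In the limma fit 3077 of 13304 genes had a slope with age, 1871 upward and 1206 downward. The larger number upward depended on the processing, with 1696 upward and 1621 downward after median-of-ratios rescaling, and 644 upward and 1045 downward with a filter of 5 FPKM. At least 0.5 log2 per year was reached by 270 rising and 83 falling genes, and at least 1 by 18 and 22. Mup13 changed by -2.03 log2 per year (SE 0.23, limma adjusted p = 5.29e-11) and rose in 0 of the 34 strains with a wide age range. Cdkn1a rose by 1.21 (SE 0.19, adjusted p = 1.38e-06, 29 of 34 strains), Cdkn2a by 0.93 (SE 0.14, adjusted p = 1.93e-06, 32 of 34) and Lcn2 by 2.02 (SE 0.35, adjusted p = 1.38e-05, 28 of 34). Further large rises were those of the neutrophil proteins Prtn3 (1.58), S100a8 (1.54), S100a9 (1.48) and Ngp (1.20), the estrogen sulfotransferase Sult1e1 (1.25) and the secreted peptide Tff3 (1.25). Large falls beside Mup13 were those of Hamp (-1.99), Hamp2 (-1.97), Mup19 (-1.89), Mup9 (-1.88), Mup1 (-1.85), Mup10 (-1.82) and Mup17 (-1.76), all in gene families whose members share reads.

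**Figure D2:**
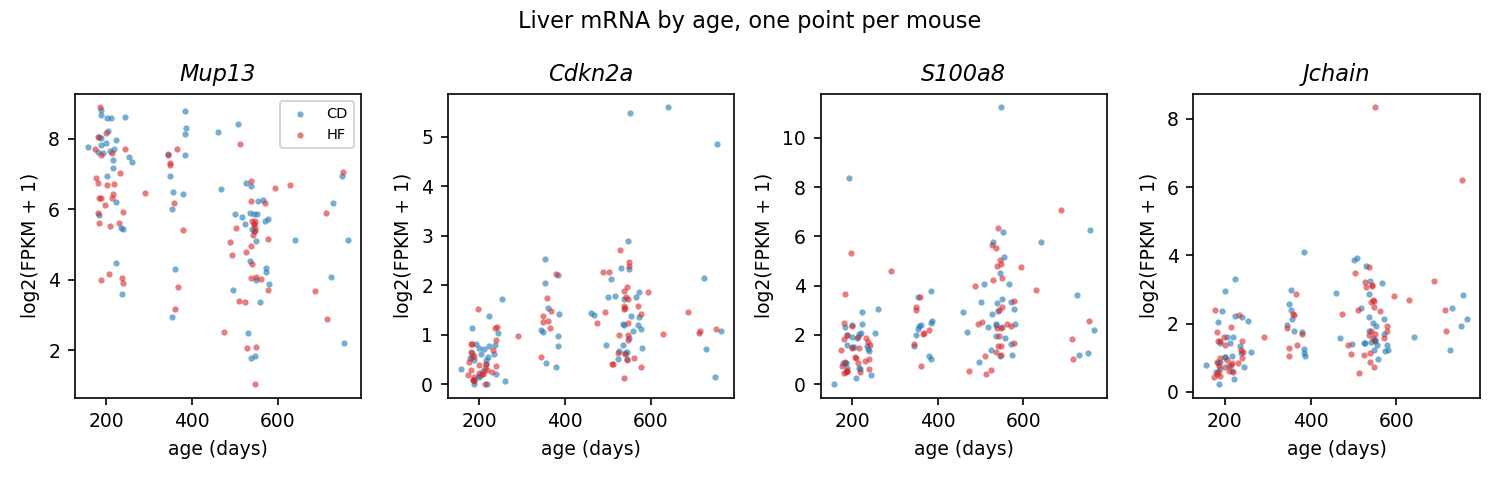
Levels of Mup13, Cdkn2a, S100a8 and Jchain as log2(FPKM + 1) on the vertical axis against age in days, with 1 point per mouse for 141 mice, coloured by diet. Mup13 falls (-2.03 log2 per year) and Cdkn2a (0.93), S100a8 (1.54) and Jchain (1.05) rise, with a few mice far above the rest.

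White blood cell markers rose together. All 10 measured neutrophil markers of 13 listed rose (10 adjusted over the list alone, median 0.83 log2 per year). So did 8 of 8 measured B and plasma cell markers of 16 listed on either adjustment, such as Jchain (1.05) and Mzb1 (0.74). Of 11 measured T and NK cell markers (22 listed), 10 rose on either adjustment, including Ccl5 (1.05) and Nkg7 (0.70). Of 18 Kupffer cell and macrophage markers, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Trem2 (0.85), Gpnmb (0.63) and Mpeg1 (0.66) among the risers. The camera adjusted p was 4.78e-08 for neutrophils, 3.8e-07 for B and plasma cells, 4.93e-09 for T and NK cells and 2.27e-07 for macrophages. In the same order, adjusted p = 0.179, adjusted p = 0.17, adjusted p = 0.17 and adjusted p = 0.233 with an estimated correlation. Erythroid markers rose for 4 of 5 genes on either adjustment, Hbb-bs from 118 ± 88.3 to 354.5 ± 518 FPKM (0.98), with camera adjusted p = 0.00488 and adjusted p = 0.27 with an estimated correlation. Stellate cell markers (3 of 12 rose, 4 adjusted over the list alone), sinusoidal endothelial markers (2 of 16, 1 adjusted over the list alone), cholangiocyte markers (1 of 7 on either adjustment) and hepatocyte markers (2 rose and 2 fell of 14, 4 and 5 adjusted over the list alone) were not called by camera.

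Inflammation and growth control followed. Of 17 chemokine and NF-kB target genes, 15 rose (16 adjusted over the list alone), including Icam1 (0.57) and Ccl2 (0.68), with camera adjusted p = 1.83e-10 and adjusted p = 0.155 with an estimated correlation. Of 22 acute phase genes, 13 rose and 1 fell, Hamp (19 and 1 adjusted over the list alone), with camera adjusted p = 2.27e-07 and adjusted p = 0.233 with an estimated correlation. Apcs rose by 0.83, while Saa1, which varied most (693 ± 2228 FPKM in the 7-month class), did not pass (0.93, adjusted p = 0.064). Interferon-stimulated genes rose for 12 of 36 (17 adjusted over the list alone), such as Gbp2 (0.61), with camera adjusted p = 6.02e-06 and adjusted p = 0.35 with an estimated correlation. Antigen presentation genes rose for 11 of 17 on either adjustment, such as H2-D1 (0.31) and Cd74 (0.64, a call lost without the 8 libraries that stood apart), with camera adjusted p = 1.13e-05 and adjusted p = 0.27 with an estimated correlation. Proliferation genes rose for 17 of 19 (18 adjusted over the list alone), though from low levels, Top2a from 0.306 ± 0.372 to 1.35 ± 3.93 FPKM (0.44), with camera adjusted p = 7.11e-08 and adjusted p = 0.235 with an estimated correlation. In the p53 and senescence list, 13 of 17 rose on either adjustment, Btg2 (0.81) beside Cdkn1a and Cdkn2a, with camera adjusted p = 1.41e-07 and adjusted p = 0.155 with an estimated correlation. Immediate early genes rose for 7 of 12 on either adjustment, such as Klf6 (0.52) and Myc (0.50), with camera adjusted p = 0.000848 and adjusted p = 0.235 with an estimated correlation. Of 8 glucocorticoid and metallothionein genes, 5 rose on either adjustment, including Mt2 (0.93) and Mt1 (0.76), with camera adjusted p = 0.00917 and adjusted p = 0.233 with an estimated correlation. Extracellular matrix genes rose for 10 of 24 (14 adjusted over the list alone), such as Timp1 (0.57) and Mmp12 (0.52), but Col1a1 did not pass (0.44, adjusted p = 0.0788). That list had camera adjusted p = 1.65e-05 and adjusted p = 0.35 with an estimated correlation. Ribosomal protein genes rose for 24 of 75 (49 adjusted over the list alone), Rps12 from 262 ± 39.3 to 336 ± 191 FPKM (0.30, a call lost with collection session as a factor), with camera adjusted p = 1.83e-10 and adjusted p = 0.397 with an estimated correlation.

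Falls were found among members of several metabolic lists and among major urinary proteins. The 18 measured major urinary proteins had 17 falls (18 adjusted over the list alone), and this was the 1 list that camera called with either correlation (median -1.49 log2 per year, adjusted p = 1.19e-38, and adjusted p = 0.00317 with an estimated correlation). Nuclear oxidative phosphorylation genes fell for 23 of 75 (27 adjusted over the list alone), such as Uqcrc1 from 145 ± 20.6 to 128 ± 18.7 FPKM (-0.23), with camera adjusted p = 4.33e-12 and adjusted p = 0.316 with an estimated correlation. None of 13 mitochondrially encoded genes passed limma (0 on either adjustment and 0 at an unadjusted p under 0.05), with camera adjusted p = 0.034 and adjusted p = 0.511 with an estimated correlation. Of 15 mitochondrial chaperones and proteases, 5 fell (6 adjusted over the list alone), such as Trap1 (-0.21), with camera adjusted p = 0.00223 and adjusted p = 0.179 with an estimated correlation. Of the 26 genes of the xenobiotic cytochrome P450 list, 13 fell (15 adjusted over the list alone), Cyp2e1 from 3503 ± 1103 to 2471 ± 930 FPKM (-0.64). The list had camera adjusted p = 3.79e-07 and adjusted p = 0.189 with an estimated correlation. Bile acid genes fell for 10 of 18 (1 rose and 13 fell adjusted over the list alone), such as Cyp27a1 (-0.37) and Slc27a5 (-0.33), with camera adjusted p = 3.8e-07 and adjusted p = 0.159 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (-0.10). Amino acid and urea cycle genes fell for 12 of 25 (13 adjusted over the list alone), such as Hpd (-0.45) and Hgd (-0.31), with camera adjusted p = 3.25e-07 and adjusted p = 0.233 with an estimated correlation. Fatty acid oxidation genes fell for 11 of 28 (14 adjusted over the list alone), such as Acaa1b (-0.83), with camera adjusted p = 1.17e-06 and adjusted p = 0.316 with an estimated correlation. Lipogenesis genes fell for 8 of 18 (11 adjusted over the list alone), such as Me1 (-0.67) and Fads2 (-0.57), with camera adjusted p = 2.69e-06 and adjusted p = 0.235 with an estimated correlation. Glucose genes fell for 6 of 20 and rose for 1, Igfbp1 (1.06), or 7 and 1 adjusted over the list alone, with camera adjusted p = 0.000767 and adjusted p = 0.233 with an estimated correlation. Lipid droplet and PPAR-gamma target genes (5 rose and 1 fell of 13 on either adjustment), cholesterol genes (3 fell of 24, 0 adjusted over the list alone) and glutathione and NRF2 target genes (2 rose and 8 fell of 24 on either adjustment) were not called by camera.

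Some genes known to differ between the sexes fell, in the female-biased and in the male-biased list. In the female-biased list 6 of 16 fell (7 adjusted over the list alone), such as Cyp2b13 (-0.79), with camera adjusted p = 0.00576 and adjusted p = 0.316 with an estimated correlation. In the male-biased list 5 of 12 fell (8 adjusted over the list alone), such as Ugt2b38 (-0.51), with camera adjusted p = 1.19e-05 and adjusted p = 0.17 with an estimated correlation. Of 18 clock genes 2 fell, among them Cry2 (-0.22), and 1 adjusted over the list alone, with camera adjusted p = 0.00645 and adjusted p = 0.27 with an estimated correlation. Exocrine pancreas markers fell for 1 of 13 genes, Cela1 (-0.73), and 0 adjusted over the list alone, with camera adjusted p = 0.00826 and adjusted p = 0.511 with an estimated correlation. With collection session as a factor the median of that list turned from -0.60 to 1.14.

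**Figure D3:**
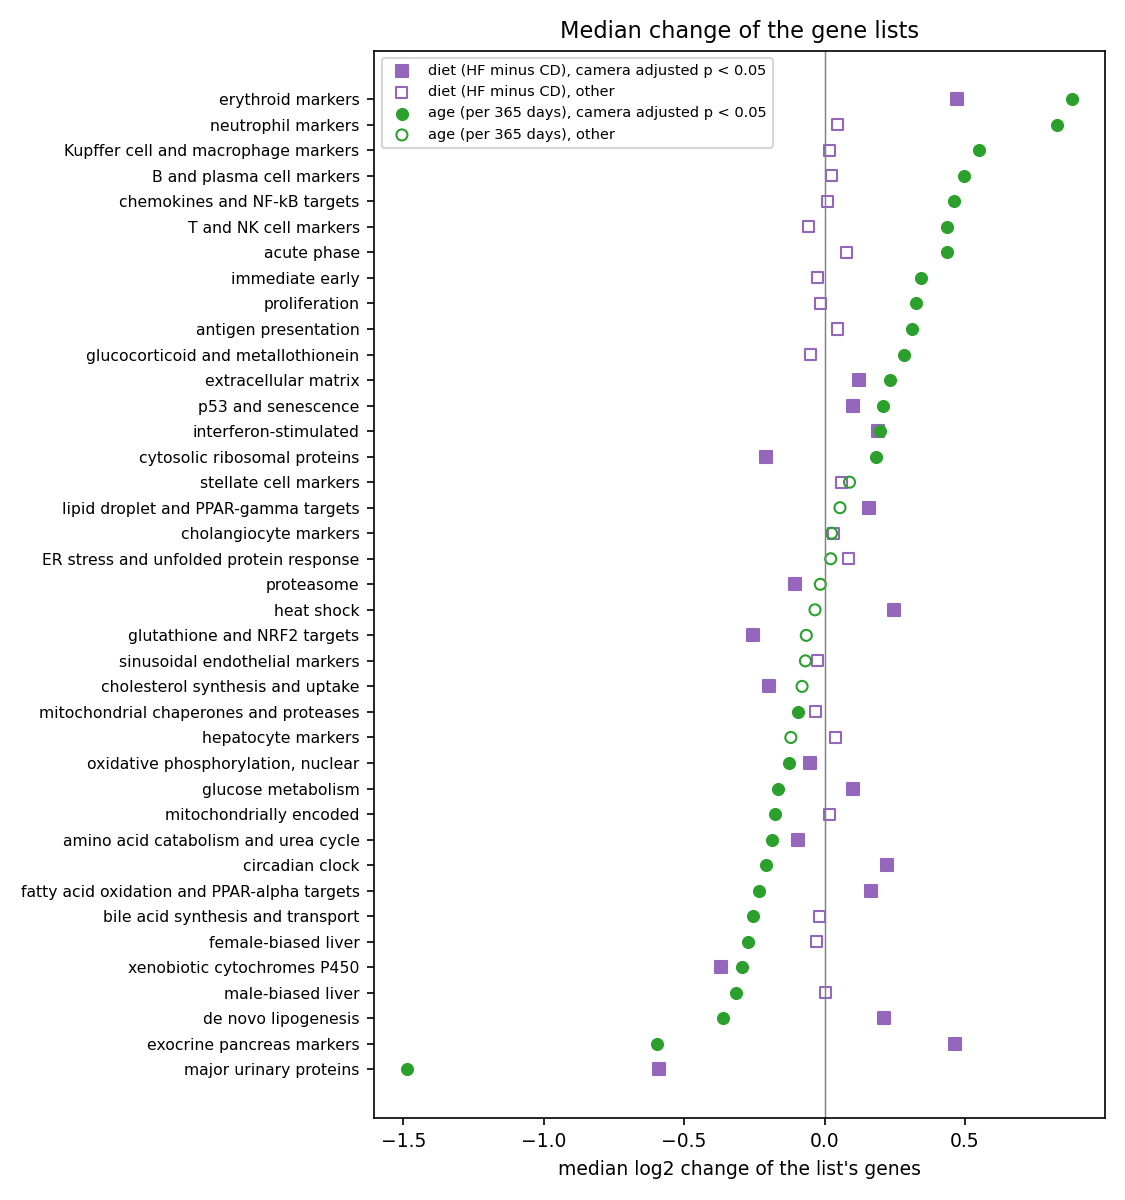
Median log2 change of the genes of each list on the horizontal axis, for diet (HF minus CD, squares) and for age (per year, circles), with filled symbols where camera with its preset correlation gave an adjusted p under 0.05. Major urinary proteins lie lowest for both (-0.59 for diet and -1.49 for age), and neutrophil and erythroid markers lie highest for age (0.83 and 0.88).

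Camera called 29 of 39 lists for age, 15 up and 14 down, and 1 with an estimated correlation, and fry called 28. The 8 libraries that stood apart on the first principal component (19.1% of the variance) came from mice aged 353 to 756 days, 6 on CD and 2 on HF, and without them 1697 genes passed for age. With collection session as a factor 1767 passed, and with flow cell as a factor 3787. Among the genes named above, at least 1 alternative ended or turned the calls of Cd74, Rps12, Igfbp1, Gbp2, Timp1, Cyp2b13, Cry2 and Cela1. Of these, Cd74, Cyp2b13, Cry2 and Cela1 did not pass without the 8 libraries, and Rps12, Igfbp1, Cyp2b13, Cry2 and Cela1 did not pass with session. Among the lists, alternatives beside the estimated correlation ended or turned the calls of mitochondrially encoded, clock, immediate early, female-biased and exocrine pancreas genes.

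Whether the diet difference changed with age was tested by the interaction of both. The genes with the smallest p included Atxn7l3b (0.24 log2 per year, SE 0.07, p = 0.000686), the metallothionein Mt2 (1.41, SE 0.44, p = 0.00181), the bile acid enzyme Cyp7b1 (0.65, SE 0.20, p = 0.00202) and the syndecans Sdc4 (0.35) and Sdc2 (0.26). Snrnp48 (0.32), Desi1 (0.22), Stx5a (0.22), Ythdf1 (0.22) and Ccdc25 (0.24) completed the 10. For all of these the slope was more positive on HF, and every adjusted p was 0.999. The count past an adjusted p of 0.05 was 0 by limma, with 476 genes at an unadjusted p under 0.05, and 0 by limma-voom, with 547. In simulated data of this design with independent normal noise, 95% of genes whose slopes differed by 1 log2 per year were recovered.

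Strain was compared to ask how far genetic background set each gene's level. The genes with the highest shares of variance between strains included enzymes, a securin, a major histocompatibility gene and a protease. Eno1b, an enolase gene copy (chromosome 18, 48045335 to 48048378), averaged 40.4 ± 21.0 FPKM in DBA/2J (n = 3) and 1.68 ± 0.422 FPKM in C57BL/6J (n = 3), with 24.2 ± 5.65 FPKM in B6D2F1 (n = 6) and 19.2 ± 3.28 FPKM in D2B6F1 (n = 4). Strain took 97.2% of its variance left after diet and age. Pttg1, a securin of chromosome separation (97.1%), Trim12a (96.8%), the thyroid hormone binding protein Crym (96.2%) and Cyp2c39 (95.6%) followed. The other genes with the highest shares were Tceanc2 (95.2%), Amn (94.1%), H2-Q2 (93.7%), RP24-470M22.10 (93.6%), Arhgef10 (93.4%), the protease Ctse (93.2%) and Mir3968 (93.1%). Reads were mapped to the C57BL/6J genome, so a DBA/2J variant can lower a count without a change in mRNA.

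By limma's moderated F-test 7747 of 13304 genes differed between strains. The median gene had 40.2% of its variance between strains, where chance alone gives 28.3%, and 1638 genes had over 50%. Of 140 mice with another mouse of their strain, 130 were closest to their own strain over the most strain-variable genes, 9 to a sister strain or the reciprocal F1, and 1 to an unrelated strain. Those genes were chosen by the labelled strains of the same mice, which favours the own strain. With collection session as a factor 4250 genes differed.

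Whether the diet difference depended on strain was tested in 132 mice of the 35 strains with both diets. Scara5, a ferritin receptor (chromosome 14, 65666403 to 65764826), was the 1 gene past the test by limma (adjusted p = 0.000806), with 2746 genes at an unadjusted p under 0.05. It averaged 8.02 FPKM on HF and 0.0628 FPKM on CD in BXD24, but 0.119 FPKM on HF and 10.9 FPKM on CD in BXD89, with 1 or 2 mice behind each value. In BXD24 the mouse on HF was 688 days old and that on CD 205. In BXD89 those on HF were 243 and 539 days old and that on CD 193. Diet and age cannot be told apart within these strains. By limma-voom the count was 0, with 3048 genes at an unadjusted p under 0.05. It was also 0 by limma with a pseudocount of 0.1 (2886 at an unadjusted p under 0.05), with a filter of 5 FPKM (1719), which leaves Scara5 out, with collection session as a factor (1726) and with the 2 males (1458). It rose to 249 with no filter, 12 with arrayWeights, 6 without the 8 libraries that stood apart and 2 or 3 under some other alternatives. In simulated data with independent normal noise, 70% of genes were recovered whose diet effects were drawn per strain with an SD of 0.5 log2.

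The parents were compared because every BXD strain carries a mosaic of their genomes. Sult3a1, a sulfotransferase (chromosome 10, 33863935 to 33879475), averaged 684 ± 411 FPKM in DBA/2J and 7.93 ± 4.87 FPKM in C57BL/6J (n = 3 each), with values between in both F1. Cyp2c39 averaged 136 ± 35.7 FPKM in DBA/2J and 4.77 ± 1.27 FPKM in C57BL/6J. Aox3, an aldehyde oxidase (chromosome 1, 58113136 to 58200698), averaged 4.27 ± 1.62 FPKM in DBA/2J and 53.7 ± 5.45 FPKM in C57BL/6J. Folr2, a folate receptor of macrophages, averaged 0.903 ± 0.546 and 18.3 ± 6.52 FPKM.

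In limma, Sult3a1 was higher in DBA/2J by 6.23 log2 (SE 0.88, adjusted p = 5.35e-08), as were Hamp2 (6.01), Cyp2c39 (4.58), Sult2a6 (4.43), Ctse (3.93) and Eno1b (3.83). Aox3 was lower (-3.27, SE 0.48, limma adjusted p = 1.67e-07), as were Cyp2a22 (-3.96), Apol7d (-3.67), Folr2 (-3.44), the mitochondrial glycine tRNA mt-Tg (-3.43) and Ildr2 (-3.37). Hamp2, Sult2a6 and Cyp2a22 have close paralogs, and the call of Hamp2 was lost without the C57BL/6J mouse of 544 days (adjusted p = 0.0592 by limma) or the DBA/2J mouse of 764 days (adjusted p = 0.0675 by limma). The calls of Apol7d and mt-Tg were lost without the DBA/2J mouse of 549 days (adjusted p = 0.0759 and 0.0632 by limma), and that of Apol7d also with the 2 males or the length slope. Limma called 2844 genes between the parents, 439 higher and 2405 lower in DBA/2J, with a median over all genes of -0.20. After rescaling by median-of-ratios factors, 54.3% of the called genes were lower in place of 84.6%, and leaving out the DBA/2J mouse of 549 days gave 805 genes.

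The F1 hybrids share their nuclear genotype and differ in which strain was the mother, so the comparison asks what follows the direction of the cross. By the naming convention the first strain is the mother. Snrpn, an imprinted splicing gene known to be expressed from the paternal copy (chromosome 7, 59982495 to 60005111), averaged 14.4 ± 1.04 FPKM in B6D2F1 (n = 6) and 5.07 ± 0.653 FPKM in D2B6F1 (n = 4). The levels in the fathers' strains were 15.6 ± 3.02 FPKM in DBA/2J and 5.30 ± 1.08 FPKM in C57BL/6J. The tRNA gene mt-Tg lies in the mitochondrial genome, which mice inherit from the mother (positions 9391 to 9458). It averaged 28.8 ± 6.55 FPKM in B6D2F1 and 1.91 ± 1.68 FPKM in D2B6F1, with 33.5 ± 2.95 FPKM in C57BL/6J and 3.27 ± 3.39 FPKM in DBA/2J.

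In limma Snrpn was higher in B6D2F1 by 1.34 log2 (SE 0.18, adjusted p = 8.94e-07), as was Snurf, which shares its transcript (1.30, adjusted p = 0.0012), and mt-Tg by 3.46 (SE 0.62, adjusted p = 0.000941). Bach2os (0.95), Mfsd5 (0.78) and Wtip (1.24) had the next smallest p by limma. The count was 599 genes, 466 higher and 133 lower in B6D2F1. Without the 8 libraries that stood apart, which include the B6D2F1 mice of 640 and 552 days, the count was 4, namely Snrpn (1.30), Snurf (1.31), mt-Tg (3.33) and Gm38393 (1.13), a gene named after its values were seen. Bach2os, Mfsd5 and Wtip then each had adjusted p = 0.408 by limma. Leaving out the B6D2F1 mouse of 640 days alone gave 5 genes, that of 552 days 6, and either D2B6F1 mouse of 540 or 545 days 9. Leaving out 1 of the other B6D2F1 mice gave 936 to 1358, and collection session as a factor gave 170.

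**Figure D4:**
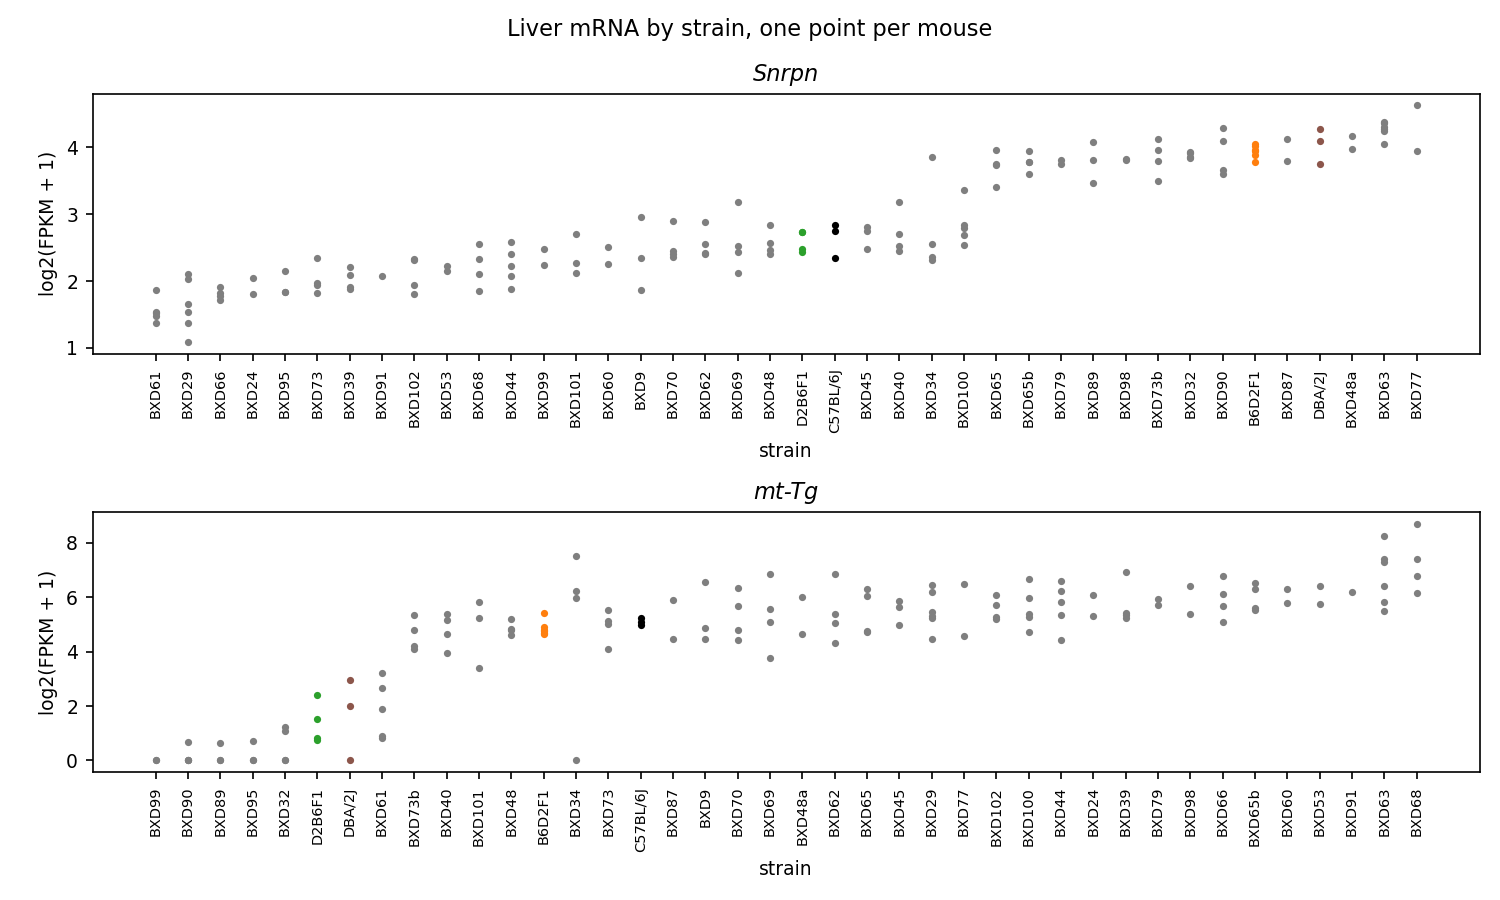
Levels of Snrpn and mt-Tg as log2(FPKM + 1) on the vertical axis for each of the 40 strains, ordered by the level, with 1 point per mouse and the parents and F1 hybrids coloured. B6D2F1 lies with DBA/2J for Snrpn (14.4 and 15.6 FPKM) and with C57BL/6J for mt-Tg (28.8 and 33.5 FPKM).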

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

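Chosen after the results were seen were the tests without the 8 libraries that stood apart, with the length slope of each library as a covariate (with its bootstrap interval), of leukocyte against other cell markers, and of the strongest other diet split. Session, rescaling and split tests were planned beforehand, and the other tests were fixed before their own values were seen, though after the patterns were. The results singled out here are differences between groups by a test of the difference, and samples far from the rest of their group.

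The diet change of Scara5 passed the test for a difference between strains (limma adjusted p = 0.000806), with single mice behind several values. No gene passed it with a pseudocount of 0.1, session as a factor, the 2 males or limma-voom, and other splits of the mice, given below, did not exclude chance. Among the 6 genes named for the reciprocal F1, the level of mt-Tg in B6D2F1 had 1 mouse apart, with a gap of 0.726 of the group's range (41.7 FPKM, the next at 29.0 FPKM). For Wtip in D2B6F1 the gap was 0.96 of the range (1.57 and 0.868 FPKM). Of 12 groups tested this way, chance picks out about 1 in 20.

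Markers of leukocytes rose with age, with 41 of 47 measured genes called and a median of 0.53 log2 per year. The 8 libraries that stood apart do not account for it alone, since 37 genes were still called without them (median 0.36). Nor do collection sessions, since the median was 0.75 with session as a factor (bootstrap 0.578 to 0.996, drawn over genes and not mice). A lower share of hepatocytes would raise all other cell types alike. The leukocyte median, however, lay 0.49 above that of 35 stellate, endothelial and cholangiocyte markers, which was 0.04. The permutation p over genes was 1e-05, the smallest these permutations can give. It takes markers as independent, though those of a cell type move together, so it does not measure the spread between mice. Camera with an estimated correlation called none of the leukocyte lists. Erythroid markers rose too, for 4 of 5 genes. Blood left in the tissue after perfusion therefore stays open, beside age itself, and was not tested. More leukocytes in older livers is therefore a hypothesis that these 3 tests left standing.

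Of 75 cytosolic ribosomal protein genes, 46 were lower on HF, with a median of -0.21 over the list. The list was called by camera with its preset correlation (adjusted p = 7.36e-27) and not with an estimated one (adjusted p = 0.474 with an estimated correlation). Of 10000 random lists matched on length and level, 0% had a median as low (their central 95% ran from -0.07 to -0.01). Other short transcripts of like level thus moved less. The random genes were drawn singly, whereas the ribosomal genes move together (estimated correlation 0.876). The 0% therefore says nothing on chance or on a shift of the list as a block. Collection sessions are argued against by a median of -0.196 with session as a factor, with 41 genes called. The length trend between libraries cannot be told apart from the diet, because the median moved to -0.106 with the length slope as a covariate, with 29 genes called. The bootstrap interval (-0.10 to -0.12) held the planned bound of -0.104. It was drawn over genes and not mice, so it leaves out the spread between mice. A rule without that interval would have counted the median of -0.106 against the length trend, and the interval was added after the value was seen.

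More genes were lower than higher in DBA/2J, 84.6% of those called. Scaling between libraries may account for much of this, since the share was 54.3% (binomial 52.2 to 56.4, genes taken as independent) after median-of-ratios rescaling. It was also 50.9% with the 2 males, 1 of each parent, added and no rescaling, so the share depends on which mice are compared as well. With the length slope as a covariate the share was 61.7% (57.2 to 66.1, the same kind of interval), which leaves the length trend open. Reads of DBA/2J lost on the C57BL/6J reference would follow the allele into the BXD strains. Genes lower in DBA/2J differed between BXD strains less often than genes higher in it, by -36.7 percentage points. The shares were 50.3 and 87.0% (Fisher's exact p = 1.87e-51, genes taken as independent), and 52.8% over all genes, so the lower genes lay near the base rate. Calls due to scaling could bring them there, so such a loss among the other lower genes is not excluded. A difference between the parents themselves was not tested apart from these.

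Other splits of the mice were compared with the real one. For diet, 2 of 100 splits within strains, the real one included, called at least as many genes as the real one (1345, highest other 3773). For age the number was also 2 of 100 (3077, highest other 3228), and for strain 1 of 100 (7747, highest other 412). Each share is under 0.05, but for diet and age another split called more, so chance is unlikely and not excluded there. A single other split for diet called more genes than the real one, as a structure of the mice beyond diet could bring about. It put 7 of the 8 libraries that stood apart in 1 group, where the real split has 6 on CD, but called 2993 genes without them (the real split 1400), so they do not account for it alone, and what it follows stays open. For the diet by age interaction the real count was 0, so 100 of 100 splits called as many by necessity (highest other 2), and the comparison says nothing about chance. Chance was not excluded for strain by diet (80 of 100, real 1, highest other 2133) or for the F1 (13 of 100, real 599, highest other 2286). The strongest other F1 split set the B6D2F1 mice of 640 and 552 days and both of 216 days against all 4 D2B6F1 mice and the B6D2F1 mice of 547 days. It kept 8 of the 10 mice apart as in the real split and moved the B6D2F1 mice of 547 days, both on HF and of 1 session. It called several times the real count, as a structure of the mice could bring about, but no test traced such a structure. The B6D2F1 libraries of 640 and 552 days, which stood apart, lay together in its smaller group. No count without them was run for this split. The parents allow 10 splits, too few for a share under 0.05 (real 2844, highest other 62).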

How the results depend on the processing

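Across all alternatives run for each but the estimated correlation, 49 of 57 named genes called for diet and 61 of 91 for age kept their direction and call. So did 12 of 19 lists for diet and 24 of 29 for age. A gene or list that the filter of 5 FPKM removed was judged by the remaining alternatives. The 18-month against the 7-month class was not compared for lists. The interaction count was 0 by limma under each alternative run for it, with 246 to 787 genes at an unadjusted p under 0.05. Position within the collection day and the 18-month against the 7-month class were not run for it. Counts below moved over 1.5-fold, and the cause was not tested unless stated. The alternatives with repeated columns, without the mouse with a label mismatch, flow cell, limma-voom, length slope, the 8 libraries and leave-one-out were chosen after seeing the data.

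The age count was 1689 with a filter of 5 FPKM (fewer genes tested, 61.9% of the called genes lower in place of 39.2%), 1767 with session as a factor, 1470 with arrayWeights, 1899 for the 18-month against the 7-month class (fewer mice) and 1697 without the 8 libraries. The diet count was 2168 with arrayWeights. The strain count was 4294 with the filter of 5, 4250 with session and 13261 with arrayWeights. The weights did not converge, so they say little about stability.

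The parents' count was 1189 with the filter of 5, 640 with the 2 males, 6270 with arrayWeights, 4689 with the 7 repeated columns, 1108 with flow cell and 486 with the length slope. The repeated column labelled as a female DBA/2J held the values of the C57BL/6J male. Leaving out 1 mouse gave 805 to 4042, lowest without the DBA/2J mouse of 549 days, then 1011 and 1313 without the C57BL/6J mice of 537 and 544 days and 1773 without the DBA/2J mouse of 764 days. The F1 count was 170 with session, 8 without mice over 600 days, 3395 with arrayWeights, 315 by limma-voom and 4 without the 8 libraries. Leaving out 1 mouse gave 5 to 1358, with 5 and 6 without the B6D2F1 mice of 640 and 552 days and 9 without either D2B6F1 mouse of 540 or 545 days. Counts rose to 1221, 1231 and 1358 without the B6D2F1 mice of 216 days on CD and of 547 days, and to 936 without that of 216 days on HF. Rescaling moved the share of called genes that were lower from 84.6 to 54.3% between the parents and from 22.2 to 37.7% between the F1.

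The strain by diet count of 1 was 0 with a pseudocount of 0.1, with the filter of 5, with session, with the 2 males and by limma-voom. It was 249 with no filter, 2 with rescaling, 2 without mice over 600 days, 12 with arrayWeights, 3 with the 7 repeated columns, 2 without the mouse with a label mismatch and 6 without the 8 libraries. With an estimated correlation the 40 called gene lists came to 1 and the 8 called cell marker lists to 0.

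Reversed were the age change of Cela1 with session (0.313), the age median of exocrine pancreas markers with session (1.14), and the diet median of nuclear oxidative phosphorylation genes with arrayWeights (0.017) and with the length slope (0.026). Low levels are limited by depth, at 16.7 to 32.1 reads per FPKM on 1 kb.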

Other observations

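The test of imprinted genes below was chosen after the result was seen. Snrpn and mt-Tg, which followed the direction of the cross in the F1, also split the BXD strains. Strain means of Snrpn ran from 1.96 FPKM in BXD61 to 6.63 FPKM in BXD34 (4.32 FPKM without the mouse described below, which left BXD100 highest at 6.35 FPKM) and from 12.2 FPKM in BXD65 to 19.1 FPKM in BXD77, with no strain mean between. The lower group held C57BL/6J and the upper group DBA/2J. Strain means of mt-Tg were 3.60 FPKM or lower in BXD99, BXD90, BXD89, BXD95, BXD32 and BXD61, and in DBA/2J and D2B6F1, and 24.9 FPKM or higher in all other strains. The transcript of mt-Tg is shorter than the reads, so its level may depend on how reads at its ends were counted, which no test addressed, although its F1 difference was 3.33 log2 without the 8 libraries that stood apart.

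One hypothesis was that genes differing between the reciprocal F1 are imprinted genes, whose expressed copy depends on the parent it came from. Of 30 measured genes on a hand-written list of imprinted genes, 3 were called (Snrpn, Snurf and Tspan32), against 596 of the other genes (Fisher's exact p = 0.1509, odds ratio 2.36). The test neither excludes this nor shows it, since few imprinted genes were measured. Without the 8 libraries 2 of the 30 were called.

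One mouse labelled as a female BXD34 on CD had a Ddx3y level of 16.6 FPKM, a gene on the Y chromosome, and an Xist level of 0.058 FPKM. The 2 males had Ddx3y levels of 10.1 and 10.8 FPKM. Over the most strain-variable genes it was closest to DBA/2J, its mt-Tg level was 0 FPKM and its Snrpn level 13.6 FPKM. It was kept under its label in all fits but 1 alternative.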
